A study of Homo sapiens with 10 samples.

How the data were processed

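Transcript levels in 10 samples of total RNA were read on oligonucleotide expression arrays, 1 array per sample. The samples were 5 replicates of MCF-7, an established luminal breast cancer line, and 5 of MCF-7R4, a clone of it selected in BMS-554417. RNA was purified on columns, and biotin-labelled cRNA was made from 6 µg of total RNA. The labels do not say whether the replicates were separate cultures, nor whether MCF-7R4 cells were in the drug when harvested. All p-values therefore measure only the spread between these samples, which may be technical.

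The deposited values are MAS5 signals per probe set, an intensity on a linear scale that the authors had scaled per array. The submitters' processing notes name MAS5; its version, its scaling target and its detection calls are not given in the sources used here. The table holds 62 control probe sets beside those of transcripts. Checked on the values, the mean signal of an array after trimming 2% at each end lay between 120.1 and 124.3 in all 10 arrays. The number of arrays, 5 per line, limits the precision.

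Probe sets were paired with genes through the array's annotation table, and symbols were brought to those of the RefSeq gene table of assembly GRCh38.p14. A single gene symbol was found for 41097 probe sets, which name 19752 genes, while 1801 probe sets had several symbols and 11777, the controls included, had none. Symbols of 43 probe sets were updated. Probe sets with several symbols or none were left out of the gene test. The array carries no genome build, so positions served only to order the genes along each chromosome.

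Signals were transformed as log2(signal + 16) with no further normalization. Control probe sets were left out, as were probe sets whose mean log2 value over all 10 arrays lay under the 40th percentile, which corresponds to a signal of 49.0. In all 32768 probe sets passed. Each gene was represented by its probe set with the highest mean, which gave 15065 genes. The 16 added to each signal damps the noise of dim probe sets and makes the log2 differences of dim genes smaller than the ratio of their mean signals. Folds in the text are ratios of mean signals, and log2 differences are MCF-7R4 minus MCF-7. A gene's value after ± is the SD over the 5 arrays of a line.

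MCF-7R4 was compared with MCF-7 in limma (lmFit, and eBayes with a trend), two-sided, with p-values adjusted by Benjamini and Hochberg over all genes tested. A gene was called at an adjusted p under 0.05, and a further count took those that also changed at least 2-fold on the fitted log2 scale. ABCG2 and the measures of array quality were also compared by exact two-sided permutation over all assignments of 5 of the 10 arrays, whose smallest possible p is 0.00794.

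Gene lists, 34 in all, were fixed before the data were examined, as were the fit and the alternatives not named below as added. They cover drug efflux transporters, drug uptake carriers, aryl hydrocarbon receptor targets, NRF2 targets, other drug-metabolising enzymes, the IGF and insulin receptor axis, PI3K-AKT-mTOR components, ERBB receptors and ligands, and other receptor tyrosine kinases and ligands. Others hold FOXO targets, MAPK feedback and output genes, oestrogen receptor targets, luminal markers, basal and mesenchymal markers, stem-like cell markers, and proliferation genes. Further lists hold cell cycle inhibitors with D cyclins, the BCL2 family with apoptosis genes, p53 targets, the type I interferon response, antigen presentation, NF-kB and inflammatory genes, cholesterol biosynthesis and fatty acid synthesis. The rest hold glycolysis, hypoxia, the unfolded protein and ATF4 response, retinoid and nuclear receptor genes, cell adhesion and junction genes, genes next to ABCG2, markers of fibroblasts, leukocytes and endothelium, and housekeeping genes. Each was tested with camera at a preset correlation of 0.01, adjusted over the 34 lists, and again with a correlation estimated from the data. Blocks of 25 consecutive tested genes along each chromosome were tested in the same way, the smallest holding at least 10 genes.

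Genes named in the text follow a rule set beforehand. It takes 14 genes whatever their values (ABCG2, ABCB1, ABCC1, IGF1R, INSR, IGF1, IGF2, IRS1, IRS2, EGFR, ERBB2, ERBB3, ESR1 and PGR) and the 12 largest increases and 12 largest decreases among called genes whose arrays do not overlap between the lines. It adds up to 4 members of each list with the smallest adjusted p, in the direction of the list where its test passed, and then up to 2 called members going the other way. Of each block named it adds up to 4 genes with the largest change in the direction of the block. Not every gene the rule allows is described. IGF2 was not analysed here, since no probe set names it alone.

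Alternatives were a pseudocount of 1 or 64, no filter on dim probe sets or one at the 60th percentile, quantile normalization, centring each array on its median, the mean of all probe sets of a gene, and leaving out probe sets with the suffix _x_at or _s_at. Further ones were the replicate number as a block, each array left out in turn, eBayes without a trend, array weights, each probe set tested on its own, limma's treat against a 1.5-fold change, fry in place of camera, and blocks of 50 genes. After the data were seen, fits without MCF-7 replicate 2 and MCF-7R4 replicate 4, or with both of these as a block term, were added.

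The gene, list and block tests were tested on simulated data with the means and spreads of these arrays, drawn independently for each gene, in which 200 of 15065 genes, 1 list and 1 block were changed. Of the changed genes, 97.0% were recovered at 1.5-fold and 100% at 2-fold and at 4-fold, and 5.26% of the 247 genes called were false. The list and the block, shifted 1.3-fold, were both recovered, among 3 lists and 3 blocks called, so that most of those called were not the shifted ones. With genes drawn independently, the effect of correlation between genes was not tested. Computations used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.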

Results

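Transcript levels were measured on oligonucleotide arrays in 5 samples of MCF-7 and 5 of MCF-7R4. MCF-7 is a luminal, oestrogen receptor positive breast cancer line. MCF-7R4 is a clone derived from it by stepwise selection in BMS-554417, an inhibitor of the kinases of the IGF-1 receptor and the insulin receptor. The clone proliferated at 10 µM of the inhibitor, about 40-fold its reported IC50, and was also resistant to BMS-536924. The median signal of an array was 59.8 ± 1.06 in MCF-7 and 60.7 ± 1.33 in MCF-7R4 (SD, n = 5 each). Signals at the 75th percentile were 122.3 ± 1.22 and 123.5 ± 0.812.

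A sign of RNA quality moved with the line, and it stands beside every gene group below. The ratio of the 3' to the 5' control probe set of ACTB was 1.52 ± 0.0472 in MCF-7 and 1.79 ± 0.0922 in MCF-7R4 (exact permutation p = 0.00794, the smallest the design allows; adjusted over 6 array measures, 0.0476). The same ratio for GAPDH went the other way, with 1.21 ± 0.0143 in MCF-7 and 1.19 ± 0.0152 in MCF-7R4 (exact permutation p = 0.0317; adjusted p = 0.0952). The median signal differed by less than the spread between arrays (exact permutation p = 0.294; adjusted p = 0.352).

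The comparison of MCF-7R4 with MCF-7 asks which transcripts differ in a clone resistant to inhibitors of the IGF-1 and insulin receptors. All MCF-7R4 samples are of that clone, so that differences tied to resistance cannot be told apart from others of the clone. The group working on this clone is known to have asked whether the efflux transporter ABCG2 has a part in its resistance. ABCG2, which encodes the breast cancer resistance protein, rose from 139.8 ± 8.31 to 1252 ± 26.6 in signal (8.95-fold, n = 5 arrays each). IGFBP5, which encodes a binding protein of the IGFs, rose from 303 ± 13.3 to 4706.5 ± 153 (15.5-fold), while IGF1R and INSR, the genes of the drug targets, did not pass the test. Of 38 proliferation genes 34 were lower in MCF-7R4, with a median log2 difference of -0.72. At a preset correlation between genes, 8 lists were higher as groups and blocks of neighbouring genes were lower on chromosome 9 and higher on chromosome 5. With an estimated correlation only the list of drug-metabolising enzymes passed (adjusted p = 0.0409), and 0 blocks did.

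Of 15065 genes tested, 7477 (49.6%) passed an adjusted p of 0.05, 3860 higher and 3617 lower in MCF-7R4. Most of these differences were small, since 5491 of the called genes changed less than 1.5-fold on the fitted log2 scale. Past 2-fold there were 657 genes, 341 higher and 316 lower. With a pseudocount of 64 there were 411 such genes. Tested on their own, 1140 probe sets of 32768 passed 2-fold, and treat against a 1.5-fold change, with no 2-fold limit, gave 1176 genes. The arrays of the lines did not overlap for 5760 genes (38.2%), where chance gives 0.794%. The median log2 difference of all tested genes was 0.017.

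ABCG2 was read by 1 probe set, and its log2 difference was 3.03 ± 0.0475 (SE; adjusted p = 3.6e-15; exact permutation p = 0.00794, the smallest the design allows). All 5 MCF-7R4 arrays, at 1214 to 1280.0, lay above all 5 MCF-7 arrays, at 132.0 to 151.9. Among the other members of the efflux list, MVP, the main protein of vault particles and not an ABC transporter, rose from 107 ± 4.59 to 410.4 ± 17.9 (3.85-fold). ABCC5, an exporter of cyclic nucleotides, rose from 176 ± 10.9 to 493 ± 25.2 (2.80-fold), and ABCG1, an exporter of cholesterol, from 116 ± 9.22 to 282 ± 6.91 (2.43-fold). ABCB1, the gene of P-glycoprotein, went from 111 ± 19.0 to 139.5 ± 16.3 (log2 difference 0.30, adjusted p = 0.0150), while its other probe set stayed near the floor at 21.4 ± 3.99 and 24.3 ± 4.97. ABCC1 was at 151 ± 4.61 in MCF-7 and 147 ± 7.18 in MCF-7R4 and did not pass (adjusted p = 0.592). In the efflux list 8 of 16 tested members were higher, 2 were lower and 6 did not pass (9 higher and 2 lower, adjusted over the list alone). As a whole the list did not pass (camera adjusted p = 0.0720), although it passed without the filter on dim probe sets (0.0475), with the mean of all probe sets of a gene (0.0304) and with fry, and its adjusted p reached from 1.7e-09 to 0.225 over the alternatives. Of the uptake carriers, 6 of 15 tested members were higher, 2 were lower and 7 did not pass (camera adjusted p = 0.355).

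Drug-metabolising enzymes other than aryl hydrocarbon receptor targets were higher as a group: 11 of 17 tested members were higher, 0 were lower and 6 did not pass, with a median log2 difference of 0.49 (camera adjusted p = 9.4e-05). This was the only list of the 34 that also passed with an estimated correlation (adjusted p = 0.0409). CYP2J2, an epoxygenase of arachidonic acid, rose from 71.2 ± 3.45 to 295 ± 8.82 (4.14-fold). The glutathione transferases GSTM3 and MGST1 rose from 1309 ± 76.0 to 3053 ± 85.8 and from 3227 ± 172 to 5299 ± 273. CYP1A1, the classic induced gene of the aryl hydrocarbon receptor, rose from 50.9 ± 3.23 to 427 ± 17.0 (8.39-fold). AHR, the gene of the receptor itself, fell from 278 ± 35.1 to 114.5 ± 5.00. Of the targets of this receptor, 8 of 12 tested members were higher, 2 were lower and 2 did not pass (camera adjusted p = 0.0819).

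**Figure D1:**
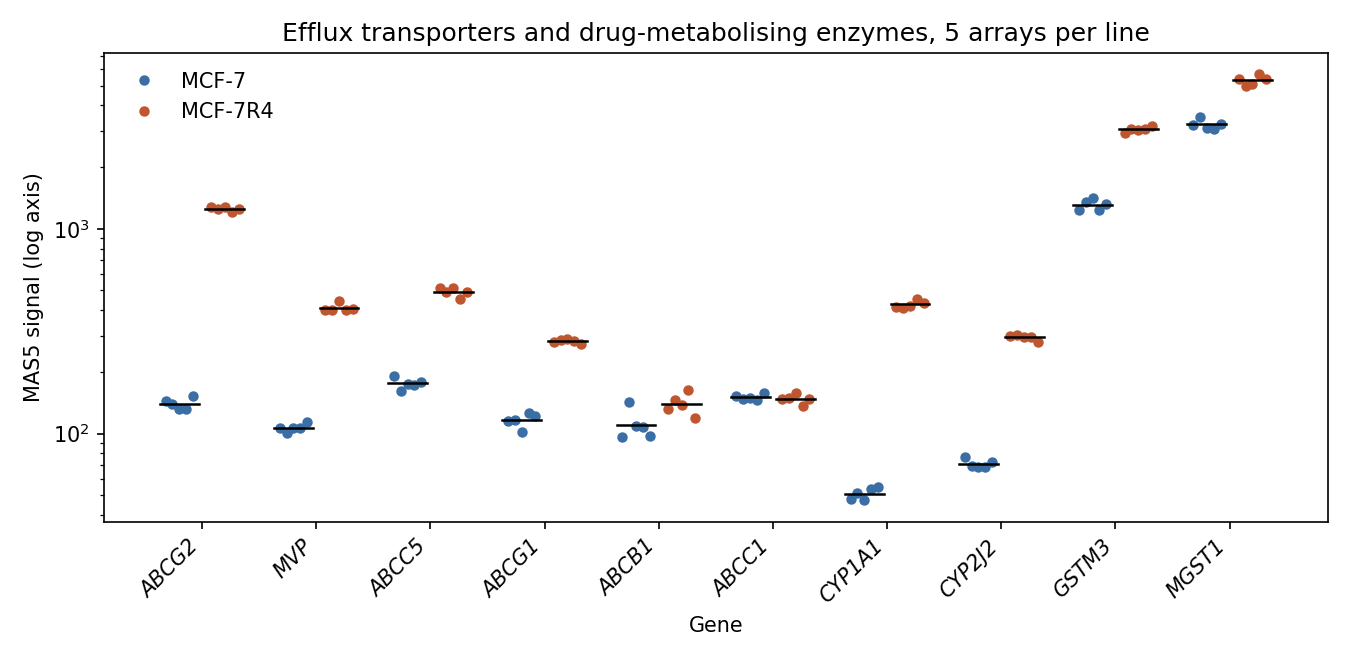
MAS5 signal on a log axis of 10 genes of drug efflux and metabolism, with each point an array, blue for MCF-7 and orange for MCF-7R4 (5 each), and black lines at the means. ABCG2 lies at 132.0 to 151.9 in MCF-7 and 1214 to 1280.0 in MCF-7R4, while the points of ABCB1 and of ABCC1 overlap.

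NRF2 targets, which serve the response to oxidants, were higher as a group: 13 of 21 tested members were higher, 3 were lower and 5 did not pass (13 higher and 4 lower, adjusted over the list alone; camera adjusted p = 0.0113). With an estimated correlation the list did not pass (adjusted p = 0.0651). TXNRD1, a thioredoxin reductase, rose from 484 ± 34.2 to 1619.8 ± 107 (3.35-fold), and PRDX1, a peroxiredoxin, from 5186 ± 190.4 to 7715 ± 206. AKR1C1 rose from 635 ± 59.1 to 1636 ± 87.2 and AKR1C3 fell from 1207 ± 102 to 436 ± 12.3, although these aldo-keto reductases are close in sequence and their probe sets can share targets. TXN, the gene of thioredoxin, fell from 3957 ± 173 to 2752 ± 89.0.

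Transcripts of the targeted receptors differed little. IGF1R was at 404 ± 50.9 in MCF-7 and 456 ± 40.1 in MCF-7R4 (log2 difference 0.18 ± 0.0863 SE, adjusted p = 0.111), and it passed without MCF-7R4 replicate 4 (log2 difference 0.23) and in 4 other settings. Another of its probe sets went the other way, with 372.8 ± 38.99 in MCF-7 and 339.0 ± 18.3 in MCF-7R4 (log2 difference -0.13). INSR was at 193 ± 33.3 in MCF-7 and 182 ± 39.3 in MCF-7R4 (adjusted p = 0.575). IGF1 was dim in both lines, with 56.2 ± 1.64 in MCF-7 and 57.5 ± 2.67 in MCF-7R4. IRS1, an adaptor of both receptors, fell from 775 ± 44.6 to 575 ± 53.7 (1.35-fold, adjusted p = 6.7e-05), and its relative IRS2 rose from 144 ± 3.74 to 289.7 ± 13.4 (2.01-fold). For IRS1 the log2 difference was -0.42 with the probe set used, and -0.25 and 0.027 with its others. IGFBP6, another binding protein of the IGFs, rose from 45.7 ± 2.30 to 257 ± 13.5, and SOCS2, a suppressor of cytokine signalling, from 193 ± 14.8 to 863 ± 30.2 (4.47-fold). Over the whole axis 5 of 24 tested members were higher, 5 were lower and 14 did not pass. Its median log2 difference was -0.037, its mean 0.30 and its test upward, so that they differed in sign, and the list did not pass (camera adjusted p = 0.800).

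ERBB3 and ERBB2, receptors of the EGFR family, rose from 799 ± 26.3 to 1572 ± 40.5 (1.97-fold) and from 235 ± 8.94 to 442 ± 9.60 (1.88-fold). EGFR rose from 161 ± 20.8 to 195 ± 16.01 (log2 difference 0.26), with arrays that overlap between the lines. Its other probe sets had log2 differences from -0.044 to 0.56. In the ERBB list 4 of 10 tested members were higher, 2 were lower and 4 did not pass (camera adjusted p = 0.685). Among other receptor tyrosine kinases and their ligands 11 of 31 tested members were higher, 4 were lower and 16 did not pass (11 higher and 5 lower, adjusted over the list alone; camera adjusted p = 0.514). In that list FGFR4, a receptor of fibroblast growth factors, rose from 58.9 ± 4.22 to 208 ± 14.7 (3.54-fold) and the ephrin receptor EPHA4 from 74.98 ± 6.35 to 216 ± 12.4 (2.88-fold).

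**Figure D2:**
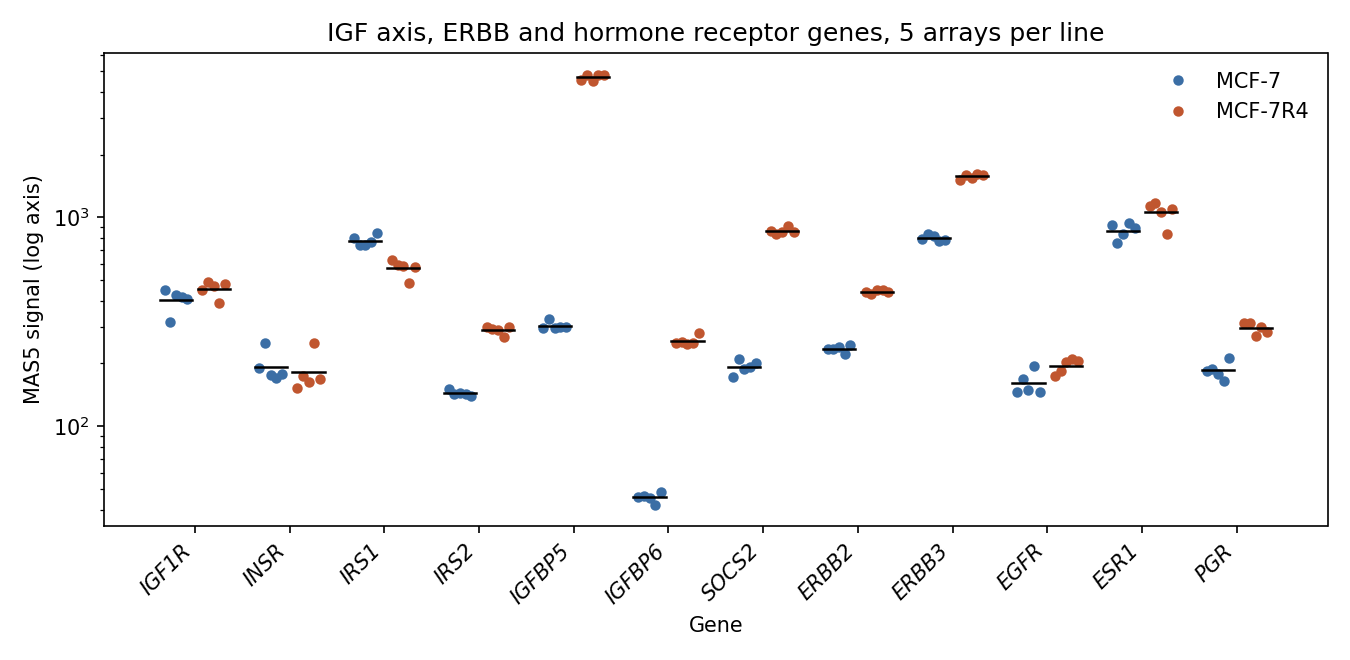
MAS5 signal on a log axis of 12 genes of the IGF axis, the ERBB family and the hormone receptors, with each point an array, blue for MCF-7 and orange for MCF-7R4 (5 each), and black lines at the means. IGFBP5 differs most (15.5-fold between the means), while the points of IGF1R, INSR, EGFR and ESR1 overlap.

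Downstream of the receptors, FOXO targets were higher as a group: 12 of 22 tested members were higher, 4 were lower and 6 did not pass (camera adjusted p = 0.0187; adjusted p = 0.326 with an estimated correlation). TXNIP, an inhibitor of thioredoxin and of glucose uptake, rose from 1047 ± 65.2 to 2569 ± 77.7 (2.45-fold), and the repressor BCL6 from 119 ± 4.58 to 240.2 ± 12.7. FOXO3, a FOXO gene itself, fell from 668 ± 25.8 to 325 ± 32.6. Of PI3K-AKT-mTOR components, 5 of 24 tested members were higher, 11 were lower and 8 did not pass (camera adjusted p = 0.355). Of MAPK feedback and output genes, 3 of 19 tested members were higher, 10 were lower and 6 did not pass, and the list did not pass (camera adjusted p = 0.0720), except without the filter on dim probe sets (0.0485) and with fry, over a range of 3.9e-09 to 0.158. Feedback and early response genes that fell were DUSP4, a MAPK phosphatase, from 479 ± 26.8 to 66.3 ± 3.91 (7.22-fold), IER3 from 1795 ± 89.1 to 329.96 ± 11.3 (5.44-fold) and PHLDA1 from 164 ± 9.19 to 66.3 ± 1.499. Past 2-fold 3 members of this list were lower and 2 higher, with EPHA4, given above, among the latter.

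Proliferation genes were lower as a group in MCF-7R4: 1 of 38 tested members was higher, 34 were lower and 3 did not pass, with a median log2 difference of -0.72 (camera adjusted p = 1.7e-15; adjusted p = 0.0563 with an estimated correlation). CCNA2, the gene of cyclin A, fell from 703 ± 18.1 to 271 ± 12.1 (2.59-fold), MKI67, the gene of the Ki-67 antigen, from 466 ± 46.4 to 178 ± 9.56 (2.62-fold). The mitotic kinase gene AURKA fell from 2449 ± 27.9 to 1106 ± 35.8, and RRM2, of ribonucleotide reductase, from 3396 ± 66.2 to 1623 ± 38.2. TYMS, of thymidylate synthase, was the member that rose, from 1355 ± 92.5 to 1806 ± 84.4. Among cell cycle inhibitors and D cyclins 4 of 14 tested members were higher, 6 were lower and 4 did not pass. The median (-0.071) and the mean (0.032) differed in sign, with the test downward (camera adjusted p = 0.921). CDKN1A, which encodes the inhibitor p21, rose from 524 ± 10.6 to 814 ± 43.8, and CCND1, the gene of cyclin D1, fell from 1091 ± 105 to 540.5 ± 69.2 (2.02-fold). Of p53 targets 8 of 18 tested members were higher, 4 were lower and 6 did not pass (camera adjusted p = 0.150). Of BCL2 family and apoptosis genes 4 of 23 tested members were higher, 6 were lower and 13 did not pass (camera adjusted p = 0.802).

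**Figure D3:**
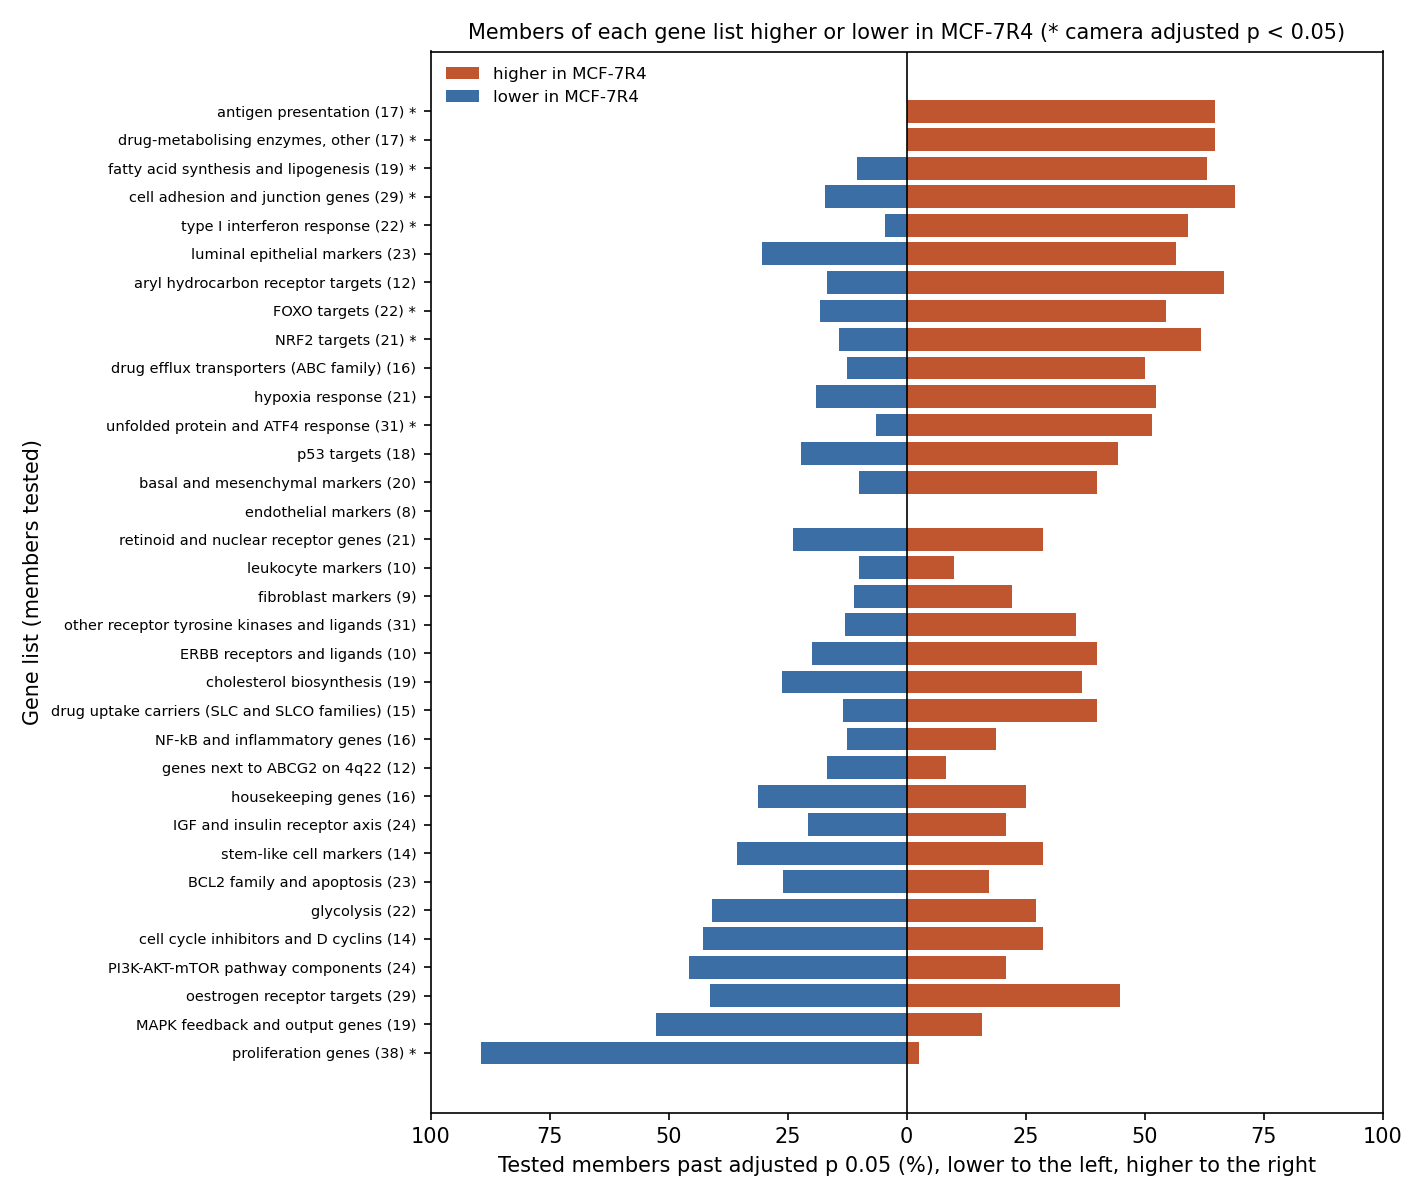
Share of the tested members of each of the 34 gene lists, in percent, that were lower (blue, to the left) or higher (orange, to the right) in MCF-7R4 past an adjusted p of 0.05, with the number tested in brackets and a star where the camera test passed at the preset correlation. Proliferation genes lie farthest to the left, with 34 of 38 members lower, and the other 8 starred lists lean to the right.

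Genes of the type I interferon response were higher as a group: 13 of 22 tested members were higher, 1 was lower and 8 did not pass (camera adjusted p = 9.1e-04; adjusted p = 0.158 with an estimated correlation). ISG20, an exonuclease, rose from 203 ± 15.8 to 1073 ± 77.9 (5.30-fold). IFITM1, whose probe set can also read close relatives, rose from 115 ± 10.4 to 321 ± 16.5 (2.78-fold), while IFI27 fell from 91.0 ± 11.7 to 43.1 ± 5.65. Antigen presentation genes moved the same way, and 11 of 17 tested members were higher, 0 were lower and 6 did not pass (camera adjusted p = 0.00119; adjusted p = 0.0651 with an estimated correlation). TAPBP, a chaperone that loads peptides, rose from 279 ± 13.2 to 655 ± 38.2 (2.35-fold), and HLA-C, which shares sequence with other class I genes, from 391 ± 21.7 to 758 ± 22.6. Of NF-kB and inflammatory genes, 3 of 16 tested members were higher, 2 were lower and 11 did not pass (2 higher and 2 lower, adjusted over the list alone; camera adjusted p = 0.685).

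Fatty acid synthesis genes were higher as a group: 12 of 19 tested members were higher, 2 were lower and 5 did not pass (camera adjusted p = 0.00210; adjusted p = 0.0563 with an estimated correlation). ACLY, which makes cytosolic acetyl-CoA, rose from 792 ± 59.6 to 2029.6 ± 137 (2.56-fold), ACSL1, which activates fatty acids, from 105 ± 5.62 to 398 ± 34.4 (3.80-fold), and SCD, a desaturase, from 4694 ± 167 to 7677 ± 242. ELOVL5, an elongase of polyunsaturated fatty acids, fell from 1329 ± 221 to 392 ± 51.8 (3.39-fold). Of cholesterol biosynthesis genes 7 of 19 tested members were higher, 5 were lower and 7 did not pass (camera adjusted p = 0.685). Of glycolysis genes 6 of 22 tested members were higher, 9 were lower and 7 did not pass (7 higher and 10 lower, adjusted over the list alone; camera adjusted p = 0.393). SLC2A1, of a glucose transporter, rose from 440.4 ± 19.6 to 1214.5 ± 73.6 (2.76-fold). In the hypoxia list 11 of 21 tested members were higher, 4 were lower and 6 did not pass (camera adjusted p = 0.0926). Unfolded protein and ATF4 response genes were higher as a group: 16 of 31 tested members were higher, 2 were lower and 13 did not pass (camera adjusted p = 0.0139; adjusted p = 0.215 with an estimated correlation). SEL1L, of the degradation of proteins from the endoplasmic reticulum, rose from 275 ± 13.6 to 702 ± 11.9 (2.55-fold). The transcription factor gene ATF4 rose from 1079.9 ± 85.9 to 1988 ± 104, but the chaperone gene HSPA5 fell from 2929.6 ± 45.1 to 1887 ± 55.4.

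Cell adhesion and junction genes were higher as a group: 20 of 29 tested members were higher, 5 were lower and 4 did not pass (camera adjusted p = 0.00251; adjusted p = 0.0651 with an estimated correlation). ALCAM rose from 1167 ± 50.3 to 5570.3 ± 191 (4.77-fold), CEACAM6 from 224 ± 13.2 to 1243 ± 97.4 (5.55-fold) and the tetraspanin gene CD9 from 2819.6 ± 145 to 5328 ± 101.4. ITGB1, the gene of integrin beta-1, fell from 1802 ± 39.3 to 1019 ± 44.2. Luminal markers moved both ways: 13 of 23 tested members were higher, 7 were lower and 3 did not pass (camera adjusted p = 0.186). TFF3, a trefoil factor, rose from 366 ± 31.4 to 1431 ± 94.9 (3.92-fold). MLPH, of melanophilin, fell from 3052 ± 87.2 to 745 ± 22.5 (4.09-fold) and the epithelial transcription factor gene ELF3 from 394 ± 18.7 to 117 ± 3.91 (3.37-fold). Of basal and mesenchymal markers 8 of 20 tested members were higher, 2 were lower and 10 did not pass (camera adjusted p = 0.211). CAV1, of caveolin-1, rose from 611 ± 34.8 to 2313 ± 89.3 (3.78-fold) and CD44, the hyaluronan receptor, from 172 ± 23.9 to 365.5 ± 36.6. In the list of stem-like cell markers 4 of 14 tested members were higher, 5 were lower and 5 did not pass (5 higher and 5 lower, adjusted over the list alone). Its median (-0.041) and mean (0.081) differed in sign, with the test upward (camera adjusted p = 0.985).

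ESR1, the gene of the oestrogen receptor, rose from 866 ± 73.4 to 1059 ± 134 (log2 difference 0.28, adjusted p = 0.0138), but with the mean of its probe sets it did not pass (log2 difference 0.051). PGR, the progesterone receptor and a classic oestrogen target, rose from 186 ± 17.1 to 295 ± 18.1 (1.59-fold, log2 difference 0.63). The other PGR probe set had 74.3 ± 3.51 in MCF-7 and 81.8 ± 5.14 in MCF-7R4 (log2 difference 0.11). Oestrogen receptor targets moved both ways: 13 of 29 tested members were higher, 12 were lower and 4 did not pass (13 higher and 13 lower, adjusted over the list alone; camera adjusted p = 0.685). CTSD, of cathepsin D, fell from 1389 ± 129 to 309.6 ± 6.62 (4.49-fold), and PKIB, an inhibitor of protein kinase A, rose from 996 ± 33.1 to 3146 ± 133 (3.16-fold). Of retinoid and nuclear receptor genes 6 of 21 tested members were higher, 5 were lower and 10 did not pass (camera adjusted p = 0.802). NR3C1, the gene of the glucocorticoid receptor, rose from 165 ± 7.36 to 1289 ± 79.3 (7.80-fold), and CRABP2, a binding protein of retinoic acid, fell from 3203 ± 83.9 to 726 ± 27.9 (4.41-fold).

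Markers of other cell types did not separate the lines as lists. Of fibroblast markers 2 of 9 tested members were higher, 1 was lower and 6 did not pass (camera adjusted p = 0.985). Their median (0.06) and mean (-0.22) differed in sign, with the test upward. Of leukocyte markers 1 of 10 tested members was higher, 1 was lower and 8 did not pass (0 higher and 0 lower, adjusted over the list alone; camera adjusted p = 0.802). Of endothelial markers 0 of 8 tested members were higher, 0 were lower and 8 did not pass (camera adjusted p = 0.693). Housekeeping genes moved both ways: 4 of 16 tested members were higher, 5 were lower and 7 did not pass (camera adjusted p = 0.802). Their median (-0.0052) and mean (0.039) differed in sign, with the test downward. GUSB, of a lysosomal glucuronidase, rose from 539 ± 21.8 to 1856 ± 101.4 (3.44-fold). ACTB, of beta-actin, fell from 16205 ± 417 to 11974 ± 353 (1.35-fold).

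Several of the genes with the largest increases on the log2(signal + 16) scale were dim in MCF-7. No fold or log2 difference is given where the mean of a line lay under a signal of 49.0, since it would rest on the 16 added. PLS3, of an actin-bundling plastin, rose from 11.4 ± 2.29 to 668 ± 78.7 and NUPR1, a stress-induced nuclear protein, from 47.5 ± 5.83 to 1537 ± 129. TNFRSF11B, the decoy receptor osteoprotegerin, rose from 70.3 ± 8.89 to 1829.8 ± 71.9 (log2 difference 4.42). UPK2 and UPK1A, of the uroplakins that line the bladder, rose from 31.3 ± 3.52 to 743 ± 74.7 and from 28.0 ± 2.73 to 392 ± 23.7. CYP26B1, which breaks down retinoic acid, rose from 26.0 ± 4.45 to 645 ± 116 and TACC1 from 131 ± 14.7 to 2083.5 ± 100.5. CLIC3 rose from 218 ± 13.1 to 2120.2 ± 139 (9.71-fold) and PREX1, an exchange factor of RAC, from 485 ± 35.3 to 4117.5 ± 189 (8.49-fold). CYP4B1, a cytochrome P450, rose from 17.9 ± 2.95 to 293 ± 13.5, but leaving out any 1 of the 5 MCF-7R4 arrays passed the choice to its other probe set, which had 42.2 ± 3.13 in MCF-7 and 163.1 ± 3.54 in MCF-7R4 over all arrays.

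Among the largest decreases on the same scale, PCDH10, a protocadherin, fell from 1362 ± 30.1 to 25.2 ± 2.17, AGR3 from 957 ± 98.8 to 40.7 ± 6.47 and ROBO1, a receptor of Slit proteins, from 308 ± 15.3 to 23.3 ± 2.51. CYBA, a subunit of NADPH oxidase, fell from 2048 ± 129 to 88.9 ± 9.43 (log2 difference -4.30), a change that its other probe set did not show (-0.069). The secreted protease gene KLK6 fell from 575 ± 36.4 to 46.0 ± 4.54, the carbonic anhydrase gene CA12 from 1486 ± 252.4 to 173 ± 21.2 (8.56-fold) and SLC6A14, of an amino acid transporter, from 1795 ± 154 to 217 ± 11.9 (8.26-fold). COL3A1 and LOXL1, genes of collagen and of its cross-linking, fell from 285 ± 25.03 to 31.5 ± 3.59 and from 962 ± 148 to 136 ± 3.19.

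Neighbouring genes moved together along several chromosomes. Of 603 blocks of 25 consecutive tested genes 73 passed, 31 higher and 42 lower in MCF-7R4. On chromosome 9, 15 of 25 blocks were lower and 0 higher, 312 of 619 genes were lower against 65 higher, and the median log2 difference was -0.17. On chromosome 5, 15 of 27 blocks were higher, with 323 of 671 genes higher against 61 lower and a median of 0.15. Further blocks were higher on chromosome 14 (6 of 20) and lower on chromosome 2 (8 of 39), the X chromosome (5 of 19), chromosome 4 (4 of 20) and chromosome 10 (4 of 24). With an estimated correlation camera passed 0 blocks, with 96 at an unadjusted p under 0.05.

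The strongest block ran from PKN3 to PRRX2 on chromosome 9, where 19 of 25 genes were lower and 0 higher (median log2 difference -0.73, adjusted p = 5.5e-07; lowest adjusted p with an estimated correlation 0.101). Its genes NUP188, of the nuclear pore, and ENDOG, a mitochondrial nuclease, fell from 542 ± 27.1 to 212 ± 15.6 and from 575 ± 48.0 to 223 ± 11.9. SH3GLB2 in this block fell from 654 ± 94.8 to 223 ± 18.9, but with probe sets that can match several transcripts left out its log2 difference was 0.018. From SH3BP4 to GPC1 on chromosome 2, 17 genes were lower and 1 higher (median -0.70, adjusted p = 1.6e-05). In it COPS8, of the COP9 signalosome, fell from 603 ± 45.4 to 197 ± 6.31 (3.07-fold) and AGAP1 from 289.7 ± 6.68 to 100.4 ± 5.98, the latter with a log2 difference of 0.049 once such probe sets were left out. Also lower was the block from UBQLN1 to S1PR3 on chromosome 9 (16 genes lower, median -0.48, adjusted p = 2.7e-04), with GOLM1, of a Golgi membrane protein, falling from 388 ± 9.64 to 53.9 ± 6.05 (7.20-fold).

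Between NPC2 and ESRRB on chromosome 14, 15 genes were higher and 1 lower (median 0.37, adjusted p = 2.7e-04), among them the transcription factor genes JDP2, from 85.3 ± 7.56 to 529 ± 36.3 (6.20-fold), and BATF, from 319 ± 13.2 to 765 ± 15.1 (2.40-fold). From SLC26A2 to FAT2 on chromosome 5, 15 genes were higher and 1 lower (median 0.22, adjusted p = 0.00375). There GM2A, a lysosomal activator of lipid breakdown, rose from 161 ± 9.94 to 544 ± 11.1 (3.38-fold) and ANXA6, an annexin, from 99.1 ± 5.12 to 597 ± 20.96 (6.02-fold), with a log2 difference of 0.11 for its other probe set. MCCC2, which breaks down leucine, rose from 631 ± 9.52 to 1716 ± 67.4 (2.72-fold) in the block from CENPH to ANKRA2 on the same chromosome (15 genes higher and 1 lower, adjusted p = 0.00471).

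ABCG2 lies on chromosome 4 in the block from NUDT9 to C4orf17, where 6 genes were higher and 5 lower (adjusted p = 0.940). Of its neighbours in the fixed list 1 of 12 tested members was higher, 2 were lower and 9 did not pass, with a median of -0.0038, a mean of 0.018 and the test downward (camera adjusted p = 0.802). HSD17B11 rose from 125 ± 14.7 to 306 ± 32.0 (2.45-fold) and KLHL8 fell from 352 ± 10.1 to 250.4 ± 11.3.

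**Figure D4:**
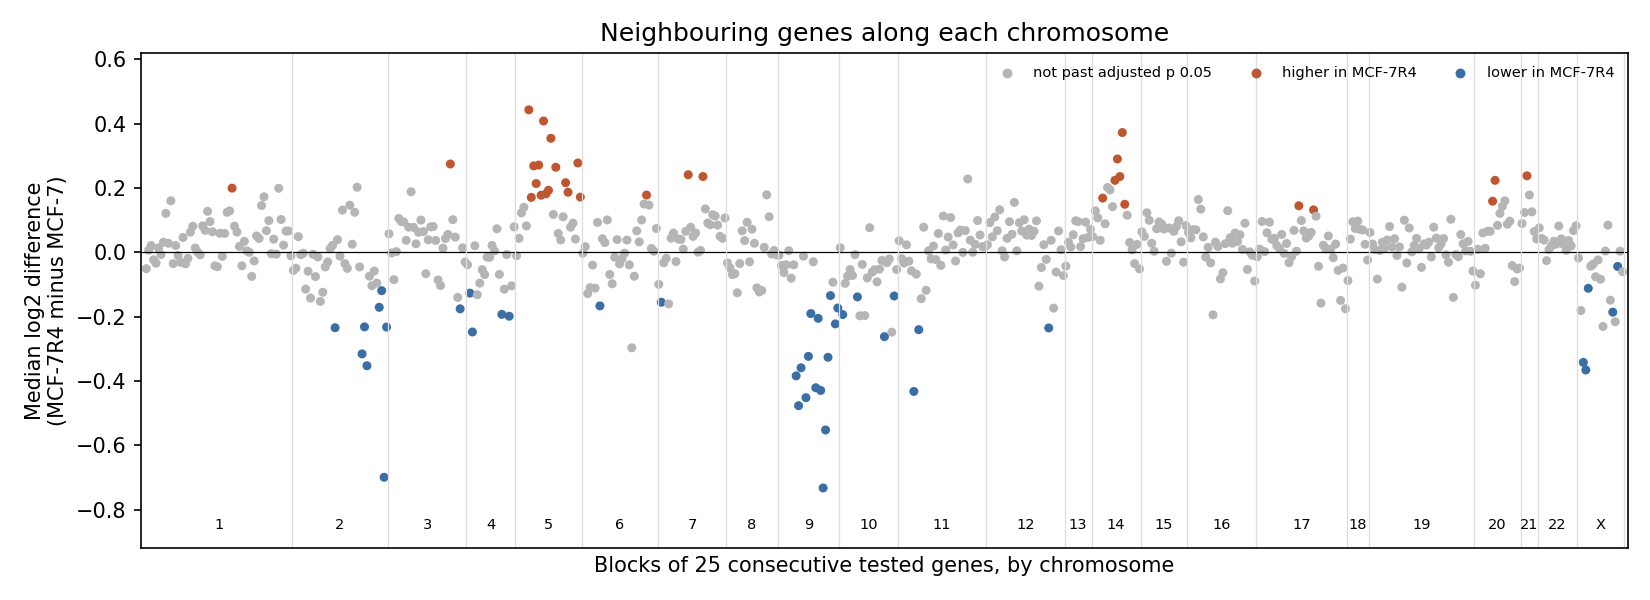
Median log2 difference (MCF-7R4 minus MCF-7) of each of 603 blocks of 25 consecutive tested genes, in order along chromosomes 1 to 22 and X, with blocks past an adjusted p of 0.05 in orange (31 higher) or blue (42 lower) and the rest in grey. Coloured points gather on chromosome 9, below 0, and on chromosome 5, above 0.

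Counts adjusted over the list alone were the same as those over all genes in 26 lists, and the 8 others are given above. Leaving out probe sets that can match several transcripts ended the calls of the NRF2 (adjusted p = 0.130), FOXO (0.172), interferon (0.0951), antigen presentation (0.130), fatty acid (0.150) and unfolded protein lists (0.213).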

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

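The test of array scaling for the proliferation genes and both tests of the arrays that deviate together were chosen only after the result was seen, as were the fits without those arrays. Other splits of the 10 arrays were fitted in the same way, 100 of the 126 possible, the split by line included. Only the split by line reached its own counts (1 of 100 each time). It gave 7477 genes past an adjusted p of 0.05 and 657 past 2-fold, and no other split gave more than 0 of either. It gave 9 lists, against at most 8 in another split, and 73 blocks, against at most 58. The splits nearest to it exchange 1 array per line (21 splits, median 6 lists and 39 blocks), keep part of the difference between the lines, and are read by a test that compares genes with one another. Splits that exchange 2 arrays (78) had a median of 1 list and 0 blocks, and at most 4 and 5. A split that mixes the lines puts their difference into the spread, so that few called genes were likely beforehand. Nor do these splits exclude chance for the lists and blocks, which also depend on correlation between genes. With an estimated correlation 1 list and 0 blocks passed.

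An array far from the other 4 of its line was found for 18 of 218 groups tested, where chance gives about 5%. In MCF-7 replicate 2, IGF1R had a signal of 316.7 (others 408.8 to 449.0) and INSR one of 251.8 (171.0 to 189.7). The same array had 326.6 for IGFBP5 (295.4 to 300.2), 1218 for LOXL1 (854.8 to 935.3) and 5515 for PRDX1 (5038 to 5153). It also had 932.5 for ATF4 (1094 to 1158) and 99.78 for HSD17B11 (127.4 to 138.5). In MCF-7R4 replicate 4, INSR had 250.5 (152.2 to 173.6), CYP26B1 445.3 (639.7 to 721.3) and CLIC3 2363 (2026 to 2102). That array also had 267.9 for FOXO3 (332.1 to 346.6), 303.0 for ELOVL5 (397.9 to 438.6) and 1809 for ATF4 (1989 to 2058). These 2 arrays held 13 of the 18. The rest were UPK1A with 350.1 in MCF-7R4 replicate 2 (396.8 to 409.7), MVP with 442.4 in MCF-7R4 replicate 3 (400.0 to 404.4) and IGFBP6 with 280.8 in MCF-7R4 replicate 5 (249.0 to 252.9). SLC2A1 had 474.0 in MCF-7 replicate 5 (423.9 to 437.2), and AGAP1 had 301.4 in MCF-7 replicate 3 (285.4 to 289.0).

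MCF-7 replicate 2 and MCF-7R4 replicate 4 deviated from their lines together: across the 15065 genes, which are not independent, their deviations correlated at r = 0.708, against at most 0.461 for the 24 other pairs between the lines. After quantile normalization r stayed at 0.6929. A scaling factor adds nearly a constant to all log2 values of an array, which r does not see, so that this cannot decide on array scaling. Handling after the RNA left the cells stays a candidate source, because over 18 probe sets for bacterial controls added at hybridisation, several of which read the same control, these arrays correlated at r = 0.9308, the highest of the 25 pairs. Over these controls each MCF-7 array had its highest correlation with a different MCF-7R4 array (0.585 to 0.931), and over the tested genes these 5 pairs correlated at 0.317, 0.708, 0.169, 0.461 and 0.160, so that handling shared across the lines stays open for the other arrays too. No biological explanation was tested, and without both arrays there were 8132 genes, 649 past 2-fold, 9 lists and 81 blocks.

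Proliferation genes were lower in MCF-7R4, with a mean log2 difference of -0.72 over 38 genes. Array scaling is argued against by size alone. The lines' median signals were close (59.8 and 60.7), and the value nearer 0 under quantile normalization or median centring was -0.7051. The list's mean was -0.7169 without the arrays that deviate together, so that it does not rest on them. As these arrays lie in different lines and deviate the same way, their part in the difference was likely small beforehand. Medians of whole chromosomes, from -0.17 to 0.15, were too small to give such a mean, so that subtracting them could not remove it (-0.7443 afterwards). The difference between the lines stays open as untested, and so do growth state, drug at harvest and the RNA behind the higher ACTB ratio, each of which goes with the line here. With an estimated correlation the list had an adjusted p of 0.0563.

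Neighbouring genes moved together in 73 blocks (12.1% of 603). Gene order had a part in it, since 0 of 100 random gene orders gave as many and none gave more than 0 blocks. Clusters of genes that share a symbol stem are argued against as the source, because 79 blocks passed with 1 gene kept per stem in a block (1507 genes left out). Co-regulated neighbours with unlike symbols stayed in, so that this cannot decide on them. Dim probe sets are argued against, since 14.62% of blocks passed with probe sets under the 60th percentile left out. A difference in copy number between the clone and its parent line may underlie such stretches, but it stays untested without DNA, as does a regional difference in regulation. With an estimated correlation no block passed (0 of 603), and other clones of the parent line were not analysed here.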

How the results depend on the processing

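The fits without MCF-7 replicate 2 and MCF-7R4 replicate 4, or with both as a block term, were chosen after seeing the data, and all other alternatives were planned. ABCG2 kept its direction and its call under all 23 alternatives run for it, with log2 differences of 2.69 to 3.15 (3.01 to 3.05 with each array left out in turn). Of 2371 values of the 104 genes described under alternatives, 2361 kept direction and side of the threshold, 3 lost the call, 5 gained it and 2 reversed. Of 847 values of lists, 811 kept both, 14 lost the call, 21 gained it and 1 reversed. Counted as kept were 27 list values and 2 gene values that passed in neither setting and had the other sign. Leaving out each array gave 6994 to 7695 genes, 646 to 665 past 2-fold, 9 lists each time and 66 to 81 blocks. The replicate number as a block gave 7073 genes, 657 past 2-fold, 9 lists and 72 blocks. The numbers do not pair the samples, since same-numbered arrays correlated in their deviations at r = -0.409 to 0.317 and 3 of 10 arrays correlated best with their own number. Blocks of 50 genes gave 65 of 308. Centring arrays on their medians gave 3542 genes higher and 3771 lower. The added fits gave 8132 genes without both arrays and 8465 with them as a block term (657 past 2-fold, 9 lists, 72 blocks).

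Genes past 2-fold numbered 411 with a pseudocount of 64, which shrinks the differences of dim genes. In place of that count, treat against a 1.5-fold change, a smaller limit, gave 1176 genes. Testing each of 32768 probe sets gave 14589 probe sets past an adjusted p of 0.05 and 1140 probe sets past 2-fold. Lists numbered 3 without _x_at and _s_at probe sets, 1 with an estimated correlation and 28 with fry, which does not compare a list with other genes. Without those probe sets adjusted p was 0.1296 for NRF2 targets, 0.172 for FOXO, 0.09507 for interferon, 0.1296 for antigen presentation, 0.1504 for fatty acid synthesis and 0.2132 for the unfolded protein list, all with fewer members tested. With an estimated correlation it was 0.06511 for NRF2 targets, antigen presentation and adhesion, 0.3263 for FOXO, 0.0563 for proliferation and fatty acid synthesis, 0.1577 for interferon and 0.2148 for unfolded protein genes, and 0 blocks passed. The estimated correlation comes from the deviations of all 10 arrays from their lines, where 1 component held 44.36% of the variance. MCF-7 replicate 2 and MCF-7R4 replicate 4 weighed most in it (0.6436 and 0.5934). The estimate was not made without these arrays, so that their part in the higher p-values was not tested. Over the 25 alternatives of each list adjusted p reached from 1.125e-19 to 0.0563 for proliferation and from 1.697e-09 to 0.04087 for drug-metabolising enzymes. The lowest was 3.037e-08 for NRF2 targets, 9.614e-07 for FOXO, 7.169e-08 for interferon, 1.198e-08 for antigen presentation, 1.697e-09 for fatty acid synthesis, 1.725e-05 for unfolded protein and 2.053e-08 for adhesion genes, all under fry, and the highest are those given above. Fibroblast markers reversed and passed under fry (4.853e-05), and had too few members tested without _x_at and _s_at probe sets for a value. Without _x_at and _s_at probe sets SH3GLB2 (0.0176) and AGAP1 (0.0493) reversed without a call, and CYBA (-0.0694) and ANXA6 (0.1106) lost theirs, as ESR1 did with the mean of its probe sets (0.0509), because other probe sets were read. Called genes shrank by over 1.5 times in 26 of 100 with that mean and in 11 of 82 without those probe sets. IGF1R gained a call under quantile normalization (0.193), array weights (0.1529), without MCF-7R4 replicate 4 (0.2275), without both deviating arrays (0.1461) and with these as a block term (0.1752); the cause was not tested. The GAPDH ratio differed by -0.03157 to -0.02096 with each array left out, and without MCF-7 replicate 1, 3 or 4 or MCF-7R4 replicate 1, 2 or 5 (6 of 10) its unadjusted exact p was no longer under 0.05, with fewer arrays. Signal over background limits dim genes: probe sets under a signal of 49.0 over all arrays were not tested, and genes under it in 1 line only were tested but have log2 differences that rest on the pseudocount.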

Other observations

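The tests of ABCG2's neighbours, of the lysosomal genes and of the urothelial markers dim in MCF-7 were chosen only after the result was seen, and the genes named in this part that the rule does not name were chosen after their values were seen. The uroplakins, plaque proteins of the bladder lining, were looked at as a family because UPK2 and UPK1A were among the largest increases. Of 5 uroplakin genes 4 rose in MCF-7R4. Beside UPK2 and UPK1A these were UPK3B, from 196.8 ± 16.8 to 1430.0 ± 72.0, whose probe set can read a related pseudogene, and UPK3A, from 61.3 ± 3.65 to 352 ± 18.7. UPK1B was dim in both lines, at 34.2 ± 3.95 and 34.5 ± 3.89 for the first of its probe sets and 36.3 ± 1.40 and 36.1 ± 2.71 for the other, and was left out by the filter. UPK2 and UPK1A were also under the filter limit in MCF-7 and passed it through their signal in MCF-7R4.

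Lysosomal genes leaned upward: 24 of 39 tested were higher, 8 lower and 7 did not pass, with a median log2 difference of 0.26. GRN, which encodes progranulin, rose from 877 ± 88.7 to 3006 ± 118.7 (3.43-fold), CTSA, of the protective protein of lysosomal sialidase, from 808 ± 63.6 to 2007 ± 91.1, and GALC, of galactosylceramidase, from 249.8 ± 36.7 to 725 ± 73.2. The proteases went apart, since CTSH rose from 826 ± 33.3 to 1641 ± 74.98 while CTSB fell from 924 ± 37.7 to 373 ± 15.4, and GLA, of alpha-galactosidase, fell from 1365 ± 81.1 to 598 ± 15.1. The list was drawn up after GUSB and GM2A, both in it, had been seen to rise, so that its camera adjusted p of 0.001673 (0.0546 with an estimated correlation) is no test of a shift of lysosomal genes as a group.

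A gain of the region around ABCG2 was a possible explanation for its rise. Its 12 tested neighbours had a median log2 difference of -0.003827 (SE 0.119, range -0.465 to 1.195), while that of ABCG2 was 3.03. A gain shared by these neighbours and large enough for the rise of ABCG2 is argued against. A limit of 0.5 for a gain, set after the result was seen, cannot decide on a smaller one. Higher blocks on chromosomes 5 and 14 had medians of only 0.44 and 0.37. A gain of ABCG2 alone and a change in its regulation stay open.

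Higher activity of the glucocorticoid receptor was a hypothesis raised by the rise of NR3C1. Its 16 tested targets had a mean log2 difference of 0.08925 (95% interval -0.19 to 0.37), with 6 higher and 4 lower (camera adjusted p = 0.583). Among them FKBP5, a target induced by the receptor, fell from 357 ± 28.7 to 156.2 ± 4.98, while NFKBIA rose from 779 ± 32.4 to 1186 ± 21.3. Members going both ways and an interval that reaches over 0.3 keep it open.

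Urothelial cells in the MCF-7R4 samples were tested as a source of the uroplakins, although the samples are of a cell line. Of 10 other urothelial markers tested 2 were higher and 4 lower, and 7 of the 10 had a signal over 100 in MCF-7 itself. The 2 higher markers were GRHL3, from 50.1 ± 3.90 to 96.1 ± 4.41, and KRT13, a keratin of that tissue, from 36.7 ± 4.09 to 69.1 ± 5.91 (adjusted p = 7.0e-07). Of the other keratins abundant there, KRT5 was at 49.0 ± 4.77 in MCF-7 and 54.1 ± 2.28 in MCF-7R4 (adjusted p = 0.144). KRT20 was at 40.6 ± 4.17 and 50.7 ± 6.48, and KRT17 was not analysed here. The 7 markers over 100 in MCF-7 could hide a small share of such cells, so that a low count over all 10, as set beforehand, was the wrong bound. Of the 3 others 2 rose, while the keratins measured stayed under 100. That count is no test, since KRT13 passed the filter only through its signal in MCF-7R4. The filter left out KRT20 and SNX31, another marker dim in both lines (17.8 ± 2.03 in MCF-7 and 17.5 ± 2.62 in MCF-7R4). These values do not decide, and such cells and a change of regulation in the clone both stay open.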
